A study of Zea mays with 68 samples.

How the data were processed

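Expression was measured by RNA-seq in organs of maize inbred B73. Per the labels' protocols, libraries were made from polyA-selected total RNA with a TruSeq kit altered to keep strand through dUTP. The submitters' processing notes name Bowtie2 2.1.0, TopHat2 2.0.8b and Cufflinks 2.1.1. The genome build, annotation and settings are not given in the sources used here. The authors deposited FPKM values (fragments per kilobase, scaled to mapped fragments) per gene, in 1 table of 109715 gene rows and 68 value columns. Whether Cufflinks counted by strand is not given in the sources used here, so it is unknown whether overlapping and antisense genes were told apart.

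A column was used only where its name matched a tissue in the labels. This held for 11 columns. The internode columns name their tissue, but their numbers run differently from those of the sample titles, so they were used as replicates without a sample of their own and are called by the number they carry. The meristem and spikelet columns were matched through the initials of the tissue names and carry the numbers of the labels. The other 57 value columns bear codes that no label explains and were not used here in any step. Nothing in the labels says that replicates came from separate plants, so p-values measure only the spread between these libraries, which may be technical. No pair of matched columns held identical values.

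Of the gene rows, 6 without a value in a matched column were left out and 64699 were at 0 in every matched column. Genes with at least 1 FPKM in at least 2 libraries were tested, 29827 in all. Depth in reads is unknown, and relative depth was read from the most frequent ratio of values below 0.3 FPKM to those of internode 6-7 library 2, a rough measure. An exact 0 can be a failed estimate. Per library, 8 to 91 genes were listed at 0 while the other libraries of the tissue were at 10 FPKM or more, and at most 3 genes lay between 0 and 0.5 FPKM in such a case. None of 58 ribosomal, tubulin and histone genes was at 0 in any library.

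Gene names came from a RefSeq table of assembly Zm-B73-REFERENCE-NAM-5.0, matched on the identifiers among its synonyms. It was used for names only, and no coordinates are given. It covered 15944 of the tested genes and gave 2201 a name, and 431 tested genes matched more than 1 reference gene. Names shared by several identifiers are uncertain, as are members of near-identical families whose reads may be shared.

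Differences were tested with limma 3.58.1 in R 4.3.3 on log2(FPKM + 1), with 1 mean per tissue, all 11 libraries in one fit, a mean-variance trend and two-sided tests. Folds on this scale understate the change of low genes. P-values were adjusted by Benjamini-Hochberg within each comparison, and a gene was called changed at an adjusted p under 0.05 and an absolute log2 difference of at least 1. Gene lists with at least 5 tested members were tested with camera at a preset correlation of 0.01, adjusted over 140 tests of 35 lists in 4 comparisons, and again with an estimated correlation. Of the 50 list calls, 5 held with the estimated correlation. A gene was tissue-enriched when its mean was at least 1 FPKM and at least 5 times that of each other tissue and its lowest library lay above the highest of every other tissue.

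The design, the alternatives and 31 lists were fixed before the data were examined, for 15 comparisons over 23 tissues. With 4 tissues matched, 2 of these could be made, and the mean of all other tissues became the mean of the other 3. The 2 comparisons of spikelets were added once it was known which columns matched. Since the reference table holds no descriptions, 28 lists were added as patterns on symbols. Some replaced lists fixed before, such as those of cell cycle and expansin genes. Others had no earlier counterpart, such as those of growth-regulating factors, HD-ZIP IV, YABBY and KANADI, and jasmonate genes. This was done after library correlations, principal components and the most abundant genes had been seen, and before any gene or list was compared between tissues. The MADS-box, meristem regulator, pathogenesis-related, pollen, C4 and benzoxazinoid lists are of the first kind. The other lists reported are of the second, apart from the flavonoid and cuticle lists, which were fixed before and were too small to test.

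Named genes followed a fixed rule. It took the 5 largest increases and 5 largest decreases among changed, named genes whose sides did not overlap, up to 3 changed members of each list read for the comparison, and up to 3 named tissue-enriched genes per tissue. For a comparison with the other tissues, every library of the tissue had to lie outside the range of their means. List members that did not pass may be named with values.

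The procedure was tested on simulated data of 29827 genes with known changes in 200. Each gene had its real mean over all libraries, the same in every tissue, and its real spread within tissues. For internodes 93% of genes changed by 2 and 100% of those changed by 3 on the log2 scale were recovered, with 9 false calls. For the meristem against the others the shares were 88% and 99%. For spikelets they were 94% and 99% against the others and 84% and 99% against the meristem. The 200 changed genes were drawn only from well-expressed genes, with a mean of at least 3 on the log2 scale used for testing. Recovery of low genes was thus not simulated, and these shares cannot be read as holding for them. Nor do they show how calls respond to an outlying library or to spread that differs between tissues. Comparisons in which a large part of the genes differ, such as those with spikelets or meristem, were not simulated. Alternatives covered the pseudocount, the filter, scaling, the tissues in the fit, the trend, a replicate block, leaving out libraries and leaving out genes with a lone 0. Tables and figures used Python with pandas, numpy, scipy and matplotlib.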

Results

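RNA-seq was used to profile organs of the maize inbred line B73, the line behind the reference genome. The labels list 68 samples of 23 tissues, and the columns of 11 libraries could be tied to 4 of these tissues by name. These were the stem internodes 6-7 and 7-8 with 3 libraries each, the vegetative meristem taken with its surrounding tissue with 2 libraries, and mature female spikelets, the flower-bearing units of the ear, with 3 libraries. The meristem and spikelet columns were read as initials of the tissue names, and every statement on these tissues rests on that reading. Mean expression reached 1 FPKM for 25703 genes in internode 6-7, 25123 in internode 7-8, 26850 in the meristem and 25247 in spikelets, and 21767 genes reached it in all 4 tissues. Total read numbers are unknown. Judged by the value of 1 read, the spikelet libraries held 0.42, 0.55 and 0.73 times the depth of internode 6-7 library 2, the meristem libraries 0.97 and 0.68 times, and the remaining internode libraries between 0.84 and 1.27 times.

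Spikelets separated from the vegetative tissues on the first principal component, which held 51.1% of the variance, and the meristem separated from the internodes on the second, which held 22.1%. Across genes, which are not independent replicates, Pearson's r lay between 0.947 and 0.977 within the internodes and reached 0.957 in the meristem and 0.934 to 0.959 in spikelets. Between meristem and spikelets it lay between 0.713 and 0.778. The internodes were not separated in this way, because r between them ran from 0.937 to 0.967. Internode 7-8 library 3 reached 0.967 with an internode 6-7 library, above its lowest value of 0.947 within its own tissue. The same held for internode 7-8 library 4 (0.949 against 0.947) and internode 6-7 libraries 3 (0.967 against 0.959) and 4 (0.964 against 0.961). Spikelet library 3 lay at 113 on the first component, apart from libraries 1 and 2 at 165 and 150. Its 10 most abundant genes held 7.15% of the summed FPKM, against 12.2% and 11.8% in those libraries.

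**Figure D1:**
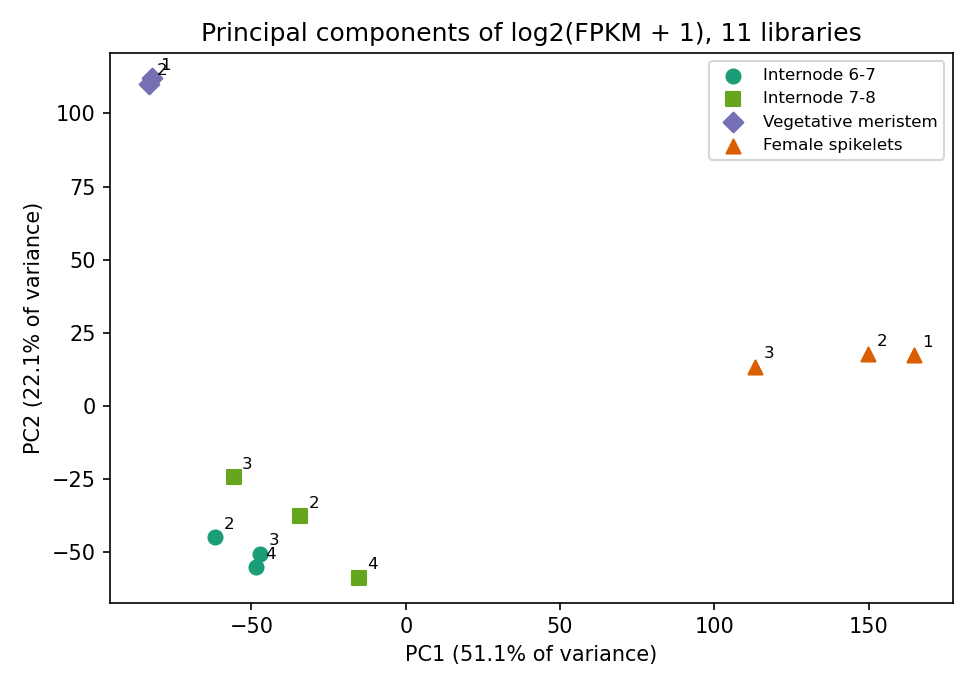
First and second principal components of log2(FPKM + 1) over 29827 genes, with axes in component units, 1 point per library and the library number beside it. The 3 spikelet libraries lie at the right, between 113 and 165 on the first component, the 2 meristem libraries at the upper left, and the 6 internode libraries together at the lower left.

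A total of 2060 genes were enriched in 1 tissue, with a mean at least 5 times that of every other tissue and no overlap between libraries. Spikelets held 1309 of these genes, the meristem 733, internode 6-7 17 and internode 7-8 1. Genes high in both internodes were left out by this rule, so the low internode counts do not show that stem transcripts are few. The internode counts were not stable, at 30 to 61 and 7 when the libraries of one replicate position were left out. Of the named genes enriched in the meristem, GRF12 (GRMZM2G119359), a growth-regulating factor, had the highest level. It was followed by SCR (GRMZM2G131516), a SCARECROW transcription factor, and EREB161 (GRMZM2G021573), an AP2/EREBP factor. GRF12 stood at 165 ± 4.31 FPKM (SD, n = 2) against 19.1 ± 2.32 (n = 3) in internode 6-7, the next tissue. SCR stood at 110 ± 29.5 FPKM (SD, n = 2) against 15.1 ± 2.67 (n = 3) in internode 7-8, and EREB161 at 54.2 ± 2.52 (n = 2) against 9.30 ± 3.80 (n = 3) there. Of the named genes enriched in spikelets, the highest were chi1 (GRMZM2G155329) at 665 ± 90.9 FPKM (SD, n = 3), the chitinase gene chiB (GRMZM2G005633) at 645 ± 102 and plt2 (GRMZM2G010868) at 409 ± 252. Their next tissues were at 37.7, 0.392 and 12.1 FPKM.

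The comparison of the internodes asked which transcripts differed between the stem samples labelled 7-8 and 6-7. Both labels carry the number 7, and whether the sampled segments overlap is not known here. Internode 7-8 held more transcript of the growth coactivator gene AN3 (GRMZM2G180246), at 281 ± 76.7 FPKM (SD, n = 3) against 93.5 ± 14.7 in internode 6-7. Less transcript was present for the beta-tubulin gene tub4 (GRMZM2G066191), at 53.2 ± 6.62 against 162 ± 22.3 FPKM, and for Dwarf1 (GRMZM2G036340), a gibberellin oxidase gene, at 5.09 ± 0.752 against 16.1 ± 1.59. CP22 (GRMZM2G077333), also listed as psbs1, a photosystem II subunit gene, stood at 8.12 ± 1.41 against 24.4 ± 3.56 FPKM. Few genes differed in all: 37 of 29827 changed, 5 of them higher and 32 lower in internode 7-8.

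The log2 differences, on the log2(FPKM + 1) scale, were 1.55 for AN3 (limma adjusted p = 0.043, Benjamini-Hochberg), -1.58 for tub4 (adjusted p = 0.029), -1.49 for Dwarf1 (adjusted p = 0.029) and -1.48 for CP22 (adjusted p = 0.043). The other named genes that fell were GR2b (GRMZM2G142705), at -1.91 (adjusted p = 0.027), and the membrane proteolipid gene PMP3 (GRMZM2G477325), at -1.39 (adjusted p = 0.043). In each of these 6 genes the 3 libraries of one internode lay beyond all 3 of the other, as the rule for named genes required. Of all tested genes, 19.3% were separated in this way. All 6 lost the call with only these 2 tissues in the fit and in at least 4 of the 6 fits without a library, and AN3, CP22 and PMP3 also after scaling and without the filter on low values, with every direction kept. None of the 11 cellulose synthase genes passed the test, with a median of -0.58. The list as a whole ranked lower in internode 7-8 (camera adjusted p = 0.0045), a call lost with an estimated correlation (adjusted p = 0.45). No member passed among 7 COBRA-type brittle stalk genes (median -0.34, camera adjusted p = 0.17), 14 lignin enzyme genes (median -0.28, adjusted p = 0.57) or 40 auxin genes (median 0.08, adjusted p = 0.15). Nor did any of 14 expansin genes (median 0.26, mean 0.00, adjusted p = 0.39), although 1 was lower when adjusted over the list alone. The 23 cell cycle genes had a median of 0.13 with no member past the test, and their camera adjusted p of 0.043 became an adjusted p of 0.45 with an estimated correlation. The count of 37 rested on single libraries. It was 160 without internode 7-8 library 3, 7 and 8 without its libraries 2 and 4, and 16 without either library 3 or library 4 of internode 6-7.

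The vegetative meristem was set against the unweighted mean of the other 3 tissues, to describe the shoot apex. The YABBY transcription factor gene yab14 (GRMZM2G005353) stood at 40.6 ± 4.67 FPKM (SD, n = 2) in the meristem and 10.6 ± 4.66 (n = 3) in spikelets, and was listed at 0 in all 3 libraries of internode 6-7. The D-type cyclin gene cycD4 (GRMZM2G133413) stood at 37.8 ± 1.15 FPKM (n = 2), with 4.46 ± 0.806 (n = 3) in internode 7-8. In the opposite direction, tub4 held 2.94 ± 1.00 FPKM (n = 2) in the meristem, against 162, 53.2 and 77.1 in internode 6-7, internode 7-8 and spikelets.

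In total 6463 genes changed, 4888 higher and 1575 lower in the meristem. The largest increases among named genes were in yab14, with a log2 difference of 4.10 (SE 0.26), the ovate family gene OFP16 (GRMZM2G055257), with 4.06, ZAR1 (GRMZM2G446201), with 4.03, CER1 (GRMZM2G099097), with 3.99, and GRF12, with 3.82. Their limma adjusted p-values (Benjamini-Hochberg) lay between 4.6e-06 and 1e-05. The largest decreases were in the proline-rich protein gene plr354a (GRMZM2G049915), at -5.49 (SE 0.45), tub4, at -4.50, the beta-glucosidase gene glu1 (GRMZM2G016890), at -3.94, cl2-2 (GRMZM2G034724), at -3.69, and the light-harvesting gene lhcb3 (GRMZM2G155216), at -3.68. Adjusted p-values for these ranged from 4.4e-07 to 0.00099.

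Of 18 genes listed as growth-regulating factors or their interacting partners, 15 rose in the meristem and none fell, with a median log2 difference of 1.93 (camera adjusted p = 2.3e-07). The call was lost with an estimated correlation (adjusted p = 0.33). Besides GRF12, the gene listed as atGRF5 and GRF7 (GRMZM5G850129) rose by 2.71 and GRF6 (GRMZM2G041223) by 2.40. Of the names on this list, 4 are each shared by 2 identifiers, so single members are less certain than the group. Of 23 meristem regulators 7 rose and 2 fell, counts that were equal when adjusted over the list alone, but the list did not pass (median 0.39, camera adjusted p = 0.11). The risers included DLF1 (GRMZM2G067921), a flowering-time bZIP gene, by 2.89, ids1 (GRMZM5G862109), an AP2 gene of spikelet determinacy, by 2.41, and the LEAFY homologue fl1 (GRMZM2G098813), also listed as zfl1, by 2.19. Among 14 KNOX and WOX homeobox genes, ns1 (GRMZM2G069028), also listed as WOX3A, rose by 1.33 and knox3 (GRMZM2G000743) fell by 1.53. That list did not pass (camera adjusted p = 0.71), with a median of 0.11 and a downward rank, and its median was -0.09 after median-of-ratios scaling. The knotted gene kn1 (GRMZM2G017087) did not pass, at a log2 difference of 0.19.

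Cell cycle genes rose in 5 of 23 cases and fell in none (median 0.46, camera adjusted p = 0.10), and after scaling 2 rose (median 0.22). They included cycD4 by 3.49, the replication licensing gene MCM7 (GRMZM2G065205), whose libraries overlapped the range of the other means, by 1.26 and cyclin11 (GRMZM2G161382) by 1.20. None of 11 histone genes passed (median 0.18, downward rank, adjusted p = 0.81). Of 40 auxin genes 7 rose and 4 fell (median 0.48, adjusted p = 0.36). The efflux carrier gene PIN1d (GRMZM2G171702) rose by 2.50, AUX36 (GRMZM2G359924) by 2.31 and AUX15 (GRMZM2G079200) by 1.95. On the MADS-box list 14 of 16 genes fell, also when adjusted over the list alone (median -2.05, camera adjusted p = 4.6e-12, adjusted p = 0.0054 with an estimated correlation). Much of that contrast lay in spikelets. M14 (GRMZM2G102161), also listed as zmm8 and zmm14, had a log2 difference of -2.72 yet stood at 0.218 FPKM in the meristem, between the 0.125 and 0.393 of the internodes. For zap1 (GRMZM2G148693) the difference was -2.83 and for m4 (GRMZM2G032339) -2.74.

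**Figure D2:**
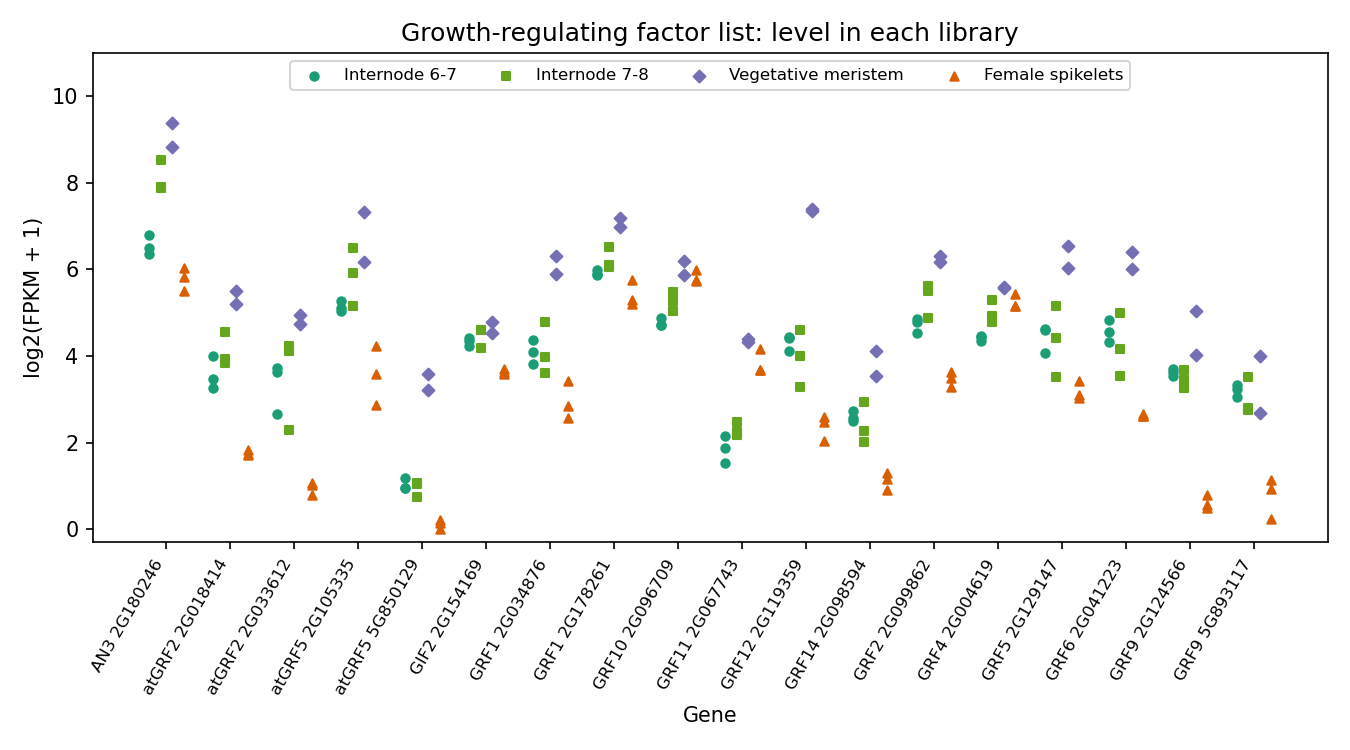
Level of each of the 18 genes of the growth-regulating factor list, as log2(FPKM + 1) on the vertical axis, with 1 point per library and 1 marker per tissue. GRF12 stands at 165 FPKM on average in the meristem and 4.25 in spikelets.

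The share of higher calls moved with scaling. It was 75.6% on the deposited values and 60.4% after median-of-ratios scaling (3500 higher and 2296 lower), which moved the median of all genes from 0.203 to -0.006. With 2 meristem libraries, the test leaned on the spread of the other tissues.

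Mature female spikelets were compared with the mean of the other 3 tissues, to describe the floral transcriptome. The MADS-box gene M14 stood at 331 ± 34.1 FPKM (SD, n = 3), m6 (GRMZM2G159397), also listed as zmm6 and zmm7, at 369 ± 22.2 and mpik32a (GRMZM2G160687), also listed as zag2, at 266 ± 15.4, with all 3 genes below 1 FPKM on average in the other tissues. The chitinase gene chiB stood at 645 ± 102 FPKM. At the other end, bx1 (GRMZM2G085381), the entry enzyme of benzoxazinoid synthesis, stood at 2.15 ± 2.32 FPKM in spikelets against 226 ± 105 (n = 3) in internode 6-7 and 94.2 ± 21.5 (n = 2) in the meristem.

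Between spikelets and the other tissues 9354 genes changed, 3491 higher and 5863 lower. The named genes with the largest increases were chiB, at a log2 difference of 8.98 (SE 0.18), M14, at 8.06, m6, at 7.81, m1 (GRMZM2G010669), at 7.74, and mpik32a, at 7.45. Each had a limma adjusted p of 9.9e-10 or lower (Benjamini-Hochberg). The largest decreases were in bx1, at -5.87 (SE 0.38, adjusted p = 1e-06), ZCN3 (GRMZM2G338454), a gene of the FT and TFL1 family, at -5.49, and 3 further MADS genes that were not on the list. These were m20 (GRMZM2G059102), at -5.28, MADS34 (GRMZM2G137510), at -4.79, and m19 (GRMZM2G370777), also listed as tunicate1, at -4.36. Expression of m20 was 3.96 ± 1.52 FPKM in spikelets and 274 ± 60.2 (n = 2) in the meristem.

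All 16 MADS-box genes on the list rose, also when adjusted over the list alone, with a median of 5.32 (camera adjusted p = 5.1e-19, adjusted p = 0.0018 with an estimated correlation). Expansin genes, which encode cell wall loosening proteins, rose in 13 of 14 cases (median 2.01, camera adjusted p = 1.1e-07, adjusted p = 0.037 with an estimated correlation). The leading members were expa1 (GRMZM2G339122), by 3.34, expA3 (GRMZM2G074585), by 3.25, and expB6 (GRMZM2G176595), by 3.18. Of 5 pathogenesis-related genes 3 rose and 1 fell, also when adjusted over the list alone (median 1.99, camera adjusted p = 0.022, but adjusted p = 0.25 with an estimated correlation and 0.062 after scaling). Chitinase chiA (GRMZM2G051943) rose by 2.73, while the defensin gene DEF1 (GRMZM2G153488) fell by 2.03. Cell cycle genes fell in 11 of 23 cases and rose in none (median -0.79, camera adjusted p = 0.0066, but adjusted p = 0.38 with an estimated correlation). MCM7 fell by 2.31, MCM6 (GRMZM2G021069) by 2.11 and pcna1 (GRMZM2G030523), the replication clamp gene, by 2.06.

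Among pollen, pectin and profilin genes 2 of 6 rose and 1 fell, also when adjusted over the list alone (median 0.65, camera adjusted p = 0.063). The actin-binding profilin genes went both ways. GRMZM2G140455, named Profilin, had a log2 difference of -3.67, while prf3 (GRMZM5G876285) rose by 2.48 and prf2 (GRMZM2G109842) by 2.34. Among 13 light-harvesting and photosystem genes 1 rose and 1 fell (median -0.04, upward rank, camera adjusted p = 0.56). CP22 rose by 2.27. The gene that fell, lhcb7 (GRMZM2G402936), at a log2 difference of -1.45, passed neither when adjusted over the list alone nor after scaling, and stood at 82.4 FPKM in spikelets, above the 47.0 of the meristem. The flavonoid list, with 4 of 10 members past the filter on low values, and the cuticle list, with 4 of 4, were not tested as lists. Chalcone synthase c2 (GRMZM2G422750) rose by 3.42 and A1 (GRMZM2G026930) by 2.41, whereas bz2 (GRMZM2G016241) fell by 1.46. The wax gene glossy2 (GRMZM2G098239) rose by 2.32.

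**Figure D3:**
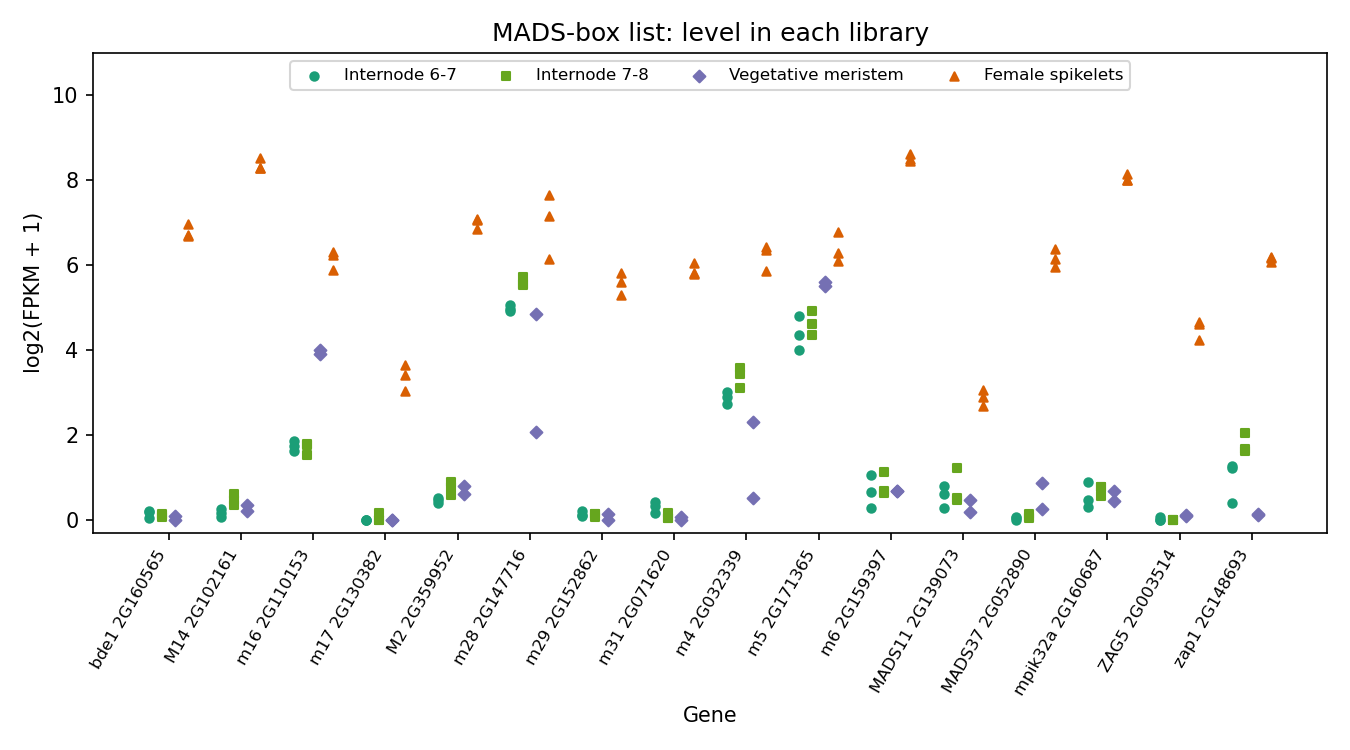
Level of each of the 16 genes of the MADS-box list, as log2(FPKM + 1) on the vertical axis, with 1 point per library and 1 marker per tissue. Spikelet libraries lie above the internodes and meristem in each gene, with means of 331 FPKM for M14 and 369 for m6.

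Scaling changed which direction held more genes. Higher calls made up 37.3% on the deposited values and 55.8% after median-of-ratios scaling (4833 higher and 3824 lower), with a median of all genes of -0.322 before and -0.053 after.

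A direct comparison of spikelets with the meristem contrasted a reproductive with a vegetative organ. The stress and ripening gene aba1 (GRMZM2G136910), also listed as asr1, stood at 312 ± 120 FPKM (SD, n = 3) in spikelets and 0.720 ± 0.708 (n = 2) in the meristem. ZCN3 showed the opposite, at 1.28 ± 0.946 against 167 ± 70.3 FPKM, as did EREB161, at 0.569 ± 0.173 against 54.2 ± 2.52. The photosystem II subunit gene CP22 held 1.60 ± 1.00 FPKM in the meristem and 39.0 ± 3.62 in spikelets.

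Here 11447 genes changed, 3497 higher and 7950 lower in spikelets. Among named genes the largest increases were again chiB, at 9.10, M14, at 8.09, m6, at 7.84, and m1, at 7.74, followed by aba1, at 7.50 (SE 0.41, limma adjusted p = 6e-07, Benjamini-Hochberg). ZCN3, at -6.21 (SE 0.33, adjusted p = 5.5e-07), m20, at -5.82, bHLH114 (GRMZM2G095899), at -5.52, bx1, at -5.15, and EREB161, at -5.14, had the largest decreases. MADS-box genes rose in 15 of 16 cases, also when adjusted over the list alone (median 5.55, camera adjusted p = 2.9e-19, adjusted p = 0.0018 with an estimated correlation), with mpik32a at 7.50. Meristem regulators fell in 15 of 23 cases and rose in 1, also when adjusted over the list alone (median -1.32, camera adjusted p = 0.028, but adjusted p = 0.38 with an estimated correlation). DLF1 had a log2 difference of -4.76, ub2 (GRMZM2G160917), an SBP-box gene, -3.48 and AUX22 (GRMZM2G130953), also listed as BIF1, -1.93. After scaling 9 of these regulators fell and 2 rose.

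Photosystem genes rose in 7 of 13 cases and fell in none (median 1.18, camera adjusted p = 0.00075, but adjusted p = 0.40 with an estimated correlation). CP22 rose by 4.00, the photosystem I gene psad1 (GRMZM2G024150) by 2.56 and CP24 (GRMZM2G092427) by 2.41. Reads of near-identical chlorophyll-binding genes may have been shared between members. C4 carbon fixation genes rose in 4 of 6 cases and fell in 1, also when adjusted over the list alone (median 1.75, camera adjusted p = 0.042, but adjusted p = 0.29 with an estimated correlation and 0.09 after scaling). The pyruvate phosphate dikinase gene pdk1 (GRMZM2G306345) rose by 3.06, the Rubisco activase gene rca1 (GRMZM2G162200) by 2.74 and the Rubisco small subunit gene rbcs1 (GRMZM2G098520) by 1.94. YABBY and KANADI genes, which set organ polarity, went both ways, with 5 of 10 higher and 3 lower (median 0.81, camera adjusted p = 0.10). KANADI gene kan1 (GRMZM2G056400) fell by 2.34, while YAB3 (GRMZM2G106204) rose by 2.17 and yab9 (GRMZM2G074543) by 2.08. Of 40 jasmonate and oxylipin genes 5 rose and 7 fell (median 0.28, mean -0.10, upward rank, camera adjusted p = 0.13). Adjusted over the list alone 4 rose and 7 fell, and after scaling the balance turned, with 8 higher and 6 lower (median 0.58). Those that fell most were the allene oxide synthase gene aos2 (GRMZM2G002178), by 2.33, TIFY15 (GRMZM2G005954), by 2.14, and the lipoxygenase gene lox9 (GRMZM2G017616), by 2.07. Of 16 zein genes with values only 1 passed the filter on low values. This was bz15 (GRMZM2G086294), also listed as zp15, which fell by 1.29 from 1.63 ± 0.541 FPKM in the meristem.

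In this comparison 30.5% of the changed genes were higher on the deposited values and 49.1% after median-of-ratios scaling (5275 higher and 5461 lower), which moved the median of all genes from -0.359 to 0.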

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

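Leaving out genes at 0 in a single library, leaving out libraries of the tissues on the other side, and running the alternatives on the counts of changed genes in the added spikelet comparisons were chosen after the data were seen. The alternatives of the list tests were chosen before. For internode 7-8 against 6-7, the 37 changed genes became 23 with median-of-ratios scaling, 16 with only these tissues in the fit, where 4 of the 37 were shared, and 60 without genes at 0 in a single library. The causes of these shifts were not tested. Leaving out 1 library gave 7 to 160 genes, with 160 without internode 7-8 library 3, 7 and 8 without its libraries 2 and 4, and 16 without library 3 or 4 of internode 6-7. None of the 6 named genes kept its call under every setting, and none changed direction.

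For the other 3 comparisons, the count of changed genes stayed within 1.5 times under each alternative run. Leaving out libraries gave 5396 to 6650 genes for the meristem against the others, 8420 to 10733 for spikelets against the others and 10291 to 12347 for spikelets against the meristem. A lone meristem library was then assumed to vary like the other tissues. Of the named genes, 24 of 26, 26 of 27 and 26 of 27 kept their call throughout in these comparisons. Named genes were picked for large differences and do not stand for all calls. After median-of-ratios scaling, 78.5%, 78.2% and 78.2% of all changed genes kept their call. List calls fell from 50 to 5 with an estimated correlation and were 43 after scaling, 41 of them shared. Tissue-enriched genes numbered 1216 when the mean had to reach 5 FPKM, by construction a smaller set, against 2060, and 2115 to 2466 when the libraries of one replicate position were left out. The 17 genes of internode 6-7 ranged from 4 to 131 over these settings and the 1 gene of internode 7-8 from 0 to 68, with 131 and 68 reached without the rule on single libraries. A mean of at least 5 FPKM also left 464 enriched genes in the meristem and 748 in spikelets, and lowered the genes detected from 25247 to 16010 in spikelets and from 21767 to 13152 in all 4 tissues.

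Meristem and spikelet libraries share the numbers 1 and 2. Deviations of same-numbered libraries correlated at 0.025 and 0.041 across genes. The deviations of the 2 meristem libraries mirror each other, so these values cannot decide whether the numbers mark pairs. With the replicate block, 12349 genes changed between spikelets and meristem, against 11447, and 53 lists passed. Spikelet library 3 has no meristem library of its number, so the block also took it out of this comparison. Leaving that library out without a block gave 12347 genes. No paired analysis was possible from the labels for the other comparisons because the internode columns could be tied to a tissue but not to a labelled sample, so they have no replicate number from the labels. Both internodes carry the column numbers 2 to 4, which no label explains. A block on these could have been fitted, but it was not run. Low depth limits low genes most in spikelet libraries 1 and 2, at 0.42 and 0.55 of the reference depth.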

Other observations

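The genes of this part were chosen after their values were seen, and 1 test, on genes above 0 only, was chosen after the result was seen. Genes of the HD-ZIP IV family, expressed in outer cell layers, rose in the meristem in 7 of 7 cases (median 2.76, camera adjusted p = 1.8e-05, but adjusted p = 0.38 with an estimated correlation). HDZIV14_OCL14 (GRMZM2G145690) rose by 3.25 and ocl4 (GRMZM2G123140) by 2.81. Light-harvesting and photosystem genes fell there in 10 of 13 cases (median -2.30, camera adjusted p = 2.7e-07, but adjusted p = 0.28 with an estimated correlation). In internode 7-8 against 6-7 the same list had a median of -1.05 with 1 member, CP22, past the test, 3 when adjusted over the list alone and none after scaling (camera adjusted p = 1.6e-05, but adjusted p = 0.36 with an estimated correlation). The libraries of internode 7-8 stood apart in some of these genes, from 37.3 to 404 FPKM in lhcb3 and from 113 to 889 in lhcb7. In spikelets, 13 of 18 growth-regulating factor genes fell against the other tissues (median -1.90, camera adjusted p = 0.0018, but adjusted p = 0.45 with an estimated correlation).

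In spikelets against the other tissues, 2 of 7 genes of the FT and TFL1 family rose and 3 fell (camera adjusted p = 0.85), with ZCN14 (GRMZM2G373928) at 6.62 and ZCN3 at -5.49. Among 10 benzoxazinoid genes 2 rose and 4 fell, also when adjusted over the list alone (camera adjusted p = 0.43). The synthesis genes bx1 and bx2 (GRMZM2G085661) had differences of -5.87 and -3.25, while the beta-glucosidase genes glu1 and glu2 (GRMZM2G008247) rose by 3.41 and 1.74. Aquaporin genes rose in 11 of 22 cases and fell in 1 (median 1.18, camera adjusted p = 1.7e-05, but adjusted p = 0.13 with an estimated correlation), led by pip2f (GRMZM2G047368), at 4.47, and tip4d (GRMZM2G093090), at 4.25. Cystatin genes, which encode protease inhibitors, rose in 6 of 8 cases (median 1.53, camera adjusted p = 1.7e-05, but adjusted p = 0.13 with an estimated correlation).

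The 6 internode libraries allow 10 splits into 3 and 3, too few for a share under 0.05. The real split gave 37 changed genes, as many as 1 split in all, and the highest of the other splits gave 7. For spikelets against the other tissues, 100 labellings of the 11 libraries were compared, with the real one included and the others drawn. The real one gave 9354 genes, and the highest of the others gave 1498. The drawn labellings mixed libraries of different tissues in a group, which widens the spread within groups. Low counts were therefore likely for them from the outset, and no conclusion on chance is drawn from this.

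Most genes that changed between spikelets and meristem were lower in spikelets (30.5% higher). A few abundant genes are argued against as the whole cause. Without the 10 most abundant genes of each library the median log2 difference was -0.30 (-0.37 to -0.25 with a library left out). Among genes with a mean of at least 10 FPKM the higher share was 32.91% (31.54% to 33.99%). That mean was taken over all libraries, most of them vegetative. The filter thus favours genes lower in spikelets, and no conclusion on depth is drawn from it. After median-of-ratios scaling the share was 49.13%, but scaling centres the genes and would pull the share towards the middle whatever the cause. The authors' normalization and a real difference in how many genes these organs express therefore cannot be told apart here. The tissue difference itself was not tested.

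Spikelet library 3 lay nearer to the vegetative libraries than libraries 1 and 2, with a gap on the first component of 20.9% of their distance from the other tissues. Removing the 10 most abundant genes of each library left the gap at 21.3%, and keeping genes with a mean of at least 10 FPKM left it at 20.6%, which argues against both a few abundant genes and depth. Spikelet-enriched genes stood at a median of 0.753 of their level in libraries 1 and 2, which would need 24.7% of other tissue. Genes of the other tissues gained a median of 0% of their level there (upper quartile 8.40%), a set with many values at 0, and among genes above 0 the highest median over the 3 tissues was 3.23%, for the meristem (upper quartile 5.30%). Admixture of these tissues as the whole cause is thus argued against, while a spikelet stage or part that differed may remain, untested.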
